A study of Homo sapiens with 66 samples.

How the data were processed

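The series holds 66 Affymetrix arrays of total RNA from human cancer cell lines in 33 groups of 2 arrays: 10 arrays of NCI-H1581 given DMSO or 1 of 4 compounds (the inhibitor set), and 56 arrays of 14 lines given DMSO or CH5183284 (the panel), all after 24 hours. The deposited table holds GCRMA expression values, intensities on a linear scale, which the submitters' processing notes credit to GCRMA in R 2.15.1. The values run from 4.8 to 32358 in the inhibitor set and from 5 to 40578 in the panel. The lowest values differ between the sets, and so do the upper quartiles (88.2 to 96.0 against 42.0 to 50.4), so the sets were taken to be normalized apart and every test except the comparison of the NCI-H1581 responses stays within 1 set. What else was done to the values before they were deposited is not given in the sources used here. The spelling NCI-716 is that of the labels.

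Of 54675 probe sets, 41097 have 1 gene symbol in the annotation (19775 genes), 1801 several and 11777 none. Gene results use the probe sets with 1 symbol. Tests ran on log2(value + 1). A probe set had to reach a log2 value of 5 in at least 2 arrays of the fit, and each gene was represented by its probe set with the highest mean, which left 9528 genes in the inhibitor set and 11999 in the panel. The arrays place 52.7 to 53.7% of probe sets within 1.2 times the lowest value in the inhibitor set and 54.3 to 56.3% in the panel. A group with both arrays within that floor has its fold given as a minimum. Replicate arrays correlated at 0.9957 to 0.9978 in the inhibitor set and 0.9934 to 0.9972 in the panel. In the panel, 56 of 56 arrays lay closest to their own replicate, and 9 of 10 in the inhibitor set. No 2 arrays had identical values.

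Each set was fitted by group means with limma 3.58.1 (lmFit, eBayes with a trend on mean level) in R 4.3.3, so that all groups of a set share 1 estimate of a gene's spread. In the panel a gene at the floor in some lines has little spread there, which lowers its shared estimate, and each line was therefore also fitted on its own 4 arrays. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Across lines, an intercept-only limma fit of the 14 differences of line means was called at adjusted p under 0.05. A moderated F test compared the 14 line contrasts. Gene lists fixed before the data were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons of a set. Members called are counted over all genes and adjusted over the list alone. Listed genes with no probe set of 1 symbol or none past the filter are not analysed here. Differences of list means between compounds carry 95% intervals from the list means of the 10 arrays. Relations over lines used permutation tests with 100000 resamples. Similarity of responses was set beside 50 simulated sets of unchanged groups against the same DMSO arrays.

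The named genes follow a rule fixed before the data: all members of the ERK-dependent and FGF receptor lists; in each comparison with its own calls, the 10 called genes with the largest rise and the 10 with the largest fall; across lines, the 10 with the smallest p in each direction and the 10 called in the most lines; and from every other list the 4 members with the smallest p. The examples given are a part of these.

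The fits were tested on simulated data with the spread of these arrays and 50 genes planted at each fold. For CH5183284 against DMSO, adjusted p under 0.05 found 84, 98, 100 and 100% of genes planted at 1.5, 2, 4 and 8-fold, and 14 of 9328 unchanged genes, of which 0 passed the 2-fold limit. For CH5183284 against AZD4547 the shares were 78, 98, 100 and 100%, for a single line (RT-4) 52, 90, 100 and 100%, for the F test between lines 56, 100, 100 and 100%, and across lines 72, 96, 100 and 100%. With the 2-fold limit, 34% of genes planted at 2-fold were called for CH5183284 against DMSO. In the simulated arrays camera at the preset correlation called a planted falling list and did not call an unchanged one. The simulated genes vary independently, so this does not test the list calls where genes are correlated.

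The alternatives tried were quantile normalization, no filter, a filter at log2 7, the mean of a gene's probe sets, no trend, the replicate number as a block, array weights and leaving out each array or line. Across lines, arrays as replicates, single replicates and the inhibitor-set NCI-H1581 arrays were tried as well. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.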

Results

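In NCI-H1581 cells, 4 compounds were compared with DMSO after 24 hours: the FGF receptor (FGFR) inhibitors CH5183284 and AZD4547, the MEK inhibitor CH4987655 and the PI3K inhibitor CH5132799. In 14 lines, NCI-H1581 among them, CH5183284 at 1 uM was compared with DMSO. Changes are log2 differences of group means with the standard error (SE) of the limma fit in brackets, 2 arrays per group. A gene rose or fell where its adjusted p was under 0.05 and its change at least 2-fold. A log2 level under 4 lies near the floor, where the arrays measure background, so changes to or from such levels, and means over lines that include them, are minimums. The labels do not say whether the 2 arrays of a group come from separate cultures, so the p-values measure the spread between these samples, which may be technical. In the inhibitor set the labels give CH5183284, CH4987655 and CH5132799 1 dose each, 1 uM. How far each compound blocked its target at that dose was not measured here, so numbers of changed genes do not rank the pathways. The labels give AZD4547 a concentration of 0 uM, which conflicts with a treatment, so its dose is unknown here.

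With CH5183284 in NCI-H1581, the feedback regulators of ERK signalling and the ETS factors that FGFR signalling maintains lost most of their mRNA. DUSP6, the phosphatase that acts on ERK, fell by 7.96 (SE 0.14; 249-fold), and ETV5 fell at least 122-fold, to a level of 2.88 near the floor (−4.72 as the mean of its probe sets). EGR1, an immediate early transcription factor, fell by 5.91 (SE 0.16). ETV4 reached the floor of the arrays, a fall of at least 24.2-fold. SPRY2 and SPRED2, which restrain receptor signalling upstream of ERK, fell by 3.32 (SE 0.11) and 3.34 (SE 0.08). The receptor EPHA2 fell by 3.00 (SE 0.25), and MYC by 1.57 (SE 0.09). The basic leucine zipper factor MAFF fell by 4.69 (SE 0.17). FOS fell at least 5.71-fold, to the floor. CCND1, the G1 cyclin D1, fell by 1.06 (SE 0.09), a change that drops to −0.98 without 1 DMSO array. Among the ERK-dependent transcripts, 16 of the 17 measured fell, 0 rose and 1 was not passed, over all genes and also adjusted over the list alone. The list test gave an adjusted p of 8.8e-11, and 0.011 with an estimated correlation. IL17RD, an antagonist of FGFR signalling, fell by 1.65 (SE 0.18). FGFR2 was higher by 0.76 (SE 0.08; adjusted p = 8.8e-06), under the 2-fold limit.

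Other genes rose in the same arrays. TP53INP1, a stress and autophagy protein, rose by 4.12 (SE 0.20). TXNIP, which limits glucose uptake and binds thioredoxin, rose by 3.97 (SE 0.23), or 2.56 as the mean of its probe sets. CD24, a surface glycoprotein, rose by 3.66 (SE 0.25), the GABA transaminase gene ABAT by 3.61 (SE 0.17) and KLHL24 by 3.03 (SE 0.24). The receptor tyrosine kinase AXL rose by 2.55 (SE 0.09). FOXO3 rose by 1.29 (SE 0.06) and CCNG2, an atypical cyclin of resting cells, by 1.60 (SE 0.17). Of 10 FOXO targets, 5 rose, 0 fell and 5 were not passed (5 rose adjusted over the list alone), adjusted p = 0.009 and 0.17 with an estimated correlation. The interferon-stimulated genes IFIT1 and IFI6 rose by 3.18 (SE 0.16) and 2.06 (SE 0.12). In that list 3 of 9 rose, 0 fell and 6 were not passed (3 adjusted over the list alone), adjusted p = 0.0019 and 0.38 with an estimated correlation. LSS, the lanosterol synthase, rose by 1.32 (SE 0.12), the only member of 16 sterol and lipid synthesis genes to do so.

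Members of the replication, mitosis and ribosome lists fell. Of 22 G1/S and DNA replication genes, 11 fell, 0 rose and 11 were not passed, the same counts adjusted over the list alone. MCM7, part of the replicative helicase, fell by 1.77 (SE 0.08) and the flap nuclease FEN1 by 1.32 (SE 0.05). Of 23 G2 and mitosis genes, 18 fell, among them CCNB1 (−1.52, SE 0.06) and the kinase AURKA (−1.38, SE 0.07). Both list tests kept their calls with an estimated correlation (adjusted p = 0.011 and 0.028). Of 19 members of the ribosome biogenesis list, 12 fell, such as RRS1 (−2.05, SE 0.08) and PNO1 (−1.62, SE 0.07). The list test gave an adjusted p of 0.11 with an estimated correlation. In the ATF4 and amino acid list, 5 of 13 fell and 1 rose. ASNS, the asparagine synthetase, fell by 1.88 (SE 0.09) and the amino acid carrier SLC7A5 by 2.13 (SE 0.13), adjusted p = 0.24 for the list with an estimated correlation. HK2, the first enzyme of glycolysis, fell by 2.04 (SE 0.12) in a list where 6 of 16 fell and 1 rose, adjusted p = 0.40 with an estimated correlation. In the BCL2 family, BCL2L11 (BIM) rose by 1.78 (SE 0.13), with its other probe sets at 1.29 and 0.03. PMAIP1 (NOXA) fell by 3.24 (SE 0.15) and BID by 1.67 (SE 0.10). Over all 9528 genes tested, 744 rose and 707 fell, and 6275 passed adjusted p under 0.05 at any size.

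**Figure D1:**
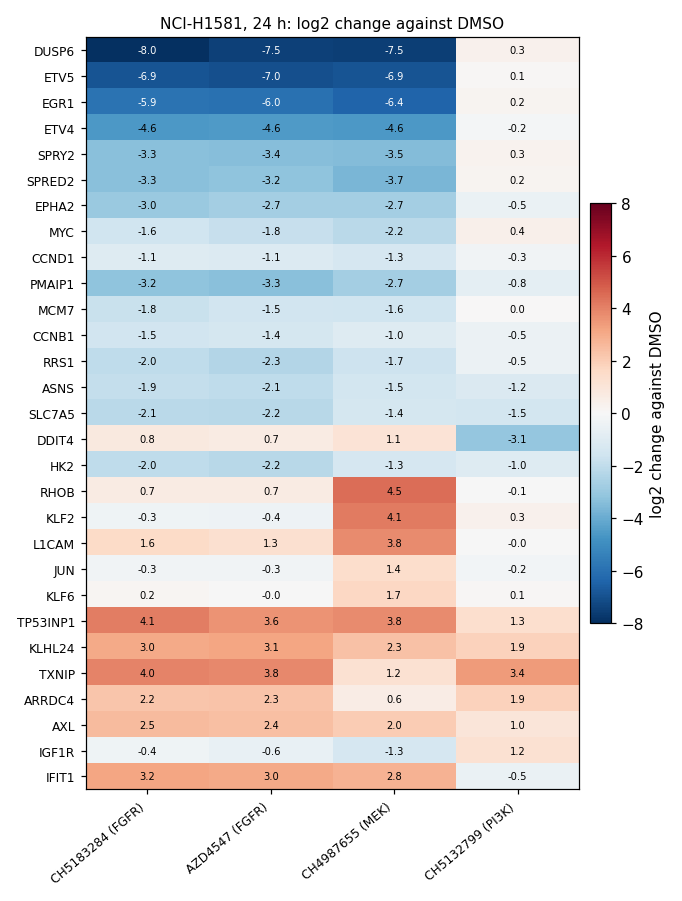
Log2 change against DMSO (colour and printed value, 2 arrays per group) of named genes (vertical axis) with each of 4 compounds (horizontal axis) in NCI-H1581. DUSP6 changes by −7.96 with CH5183284, −7.48 with AZD4547, −7.52 with CH4987655 and 0.32 with CH5132799.

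AZD4547 changed the same genes by similar amounts. DUSP6 (−7.48, SE 0.14), ETV5 (at least 130-fold, to near the floor), EGR1 (−5.98, SE 0.16), MAFF (−4.63, SE 0.17) and PMAIP1 (−3.32, SE 0.15) fell. TXNIP rose by 3.82 (SE 0.23; 2.46 as the mean of its probe sets), TP53INP1 by 3.60 (SE 0.20), IFIT1 by 3.03 (SE 0.16) and AXL by 2.40 (SE 0.09). Of the ERK-dependent transcripts, 16 of 17 fell (16 adjusted over the list alone), and of the G2 and mitosis genes 18 of 23. In all, 640 genes rose and 661 fell. Tested against each other with limma, CH5183284 and AZD4547 differed in 0 of 9528 genes at adjusted p under 0.05, with 1032 at unadjusted p under 0.05. For 99.3% of genes the 95% interval of the difference excluded 2-fold, with a median half-width of 0.22. As a group, the 22 G1/S and DNA replication genes were lower with CH5183284 than with AZD4547, by 0.11 on average (95% interval over arrays −0.17 to −0.05; adjusted p = 0.028 with an estimated correlation). The ERK-dependent transcripts differed by −0.07 (95% interval −0.16 to 0.01).

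The MEK inhibitor CH4987655 lowered the ERK-dependent transcripts too. DUSP6 fell by 7.52 (SE 0.14), ETV5 at least 120-fold, to near the floor, EGR1 by 6.42 (SE 0.16), SPRY2 by 3.48 (SE 0.11) and MYC 4.44-fold, and ETV4 fell at least 24.4-fold, to the floor. In that list 16 of 17 fell, 0 rose and 1 was not passed (16 adjusted over the list alone). PMAIP1 fell by 2.72 (SE 0.15), while AXL rose by 2.01 (SE 0.09), ERBB2 by 1.40 (SE 0.11) and IFIT1 by 2.75 (SE 0.16). IGF1R fell by 1.34 (SE 0.17). Among its largest rises were RHOB, a small GTPase, by 4.48 (SE 0.11), CLIC3 by 4.47 (SE 0.21), the transcription factor KLF2 by 4.14 (SE 0.19), the vault protein gene MVP by 4.03 (SE 0.15) and the adhesion molecule L1CAM by 3.78 (SE 0.16). CDKN2B, the CDK4/6 inhibitor p15, rose by 1.80 (SE 0.16) and KLF6 by 1.65 (SE 0.07). Of 22 G1/S genes 5 fell, and of 23 G2 and mitosis genes 8 fell, with adjusted p = 0.011 and 0.028 with an estimated correlation. In all, 624 genes rose and 422 fell.

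Tested directly, CH5183284 and CH4987655 differed in 73 genes, 19 higher and 54 lower with CH5183284. KLF2 was lower by 4.46 (SE 0.19), RHOB by 3.80 (SE 0.11), L1CAM by 2.23 (SE 0.16), the TWEAK receptor gene TNFRSF12A by 2.05 (SE 0.18), MAP1B by 1.88 (SE 0.15), JUN by 1.69 (SE 0.17) and KLF6 by 1.47 (SE 0.07). TRIB3, a pseudokinase of the stress response, was lower by 1.13 (SE 0.17), a difference of −0.98 without 1 CH5183284 array. TXNIP was higher by 2.73 (SE 0.23), its relative ARRDC4 by 1.65 (SE 0.15) and the cathepsin gene CTSF by 1.38 (SE 0.20). DUSP6 differed by −0.44 (SE 0.14; adjusted p = 0.034), under 2-fold. None of the 17 ERK-dependent transcripts differed by 2-fold at adjusted p under 0.05, and their mean differed by 0.06 (95% interval −0.02 to 0.15). The G2 and mitosis list was lower with CH5183284 by 0.33 on average, adjusted p = 3.2e-06 and 0.084 with an estimated correlation. The FOXO list had a mean of −0.12, a sign opposite to that of its test, and was not called.

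**Figure D2:**
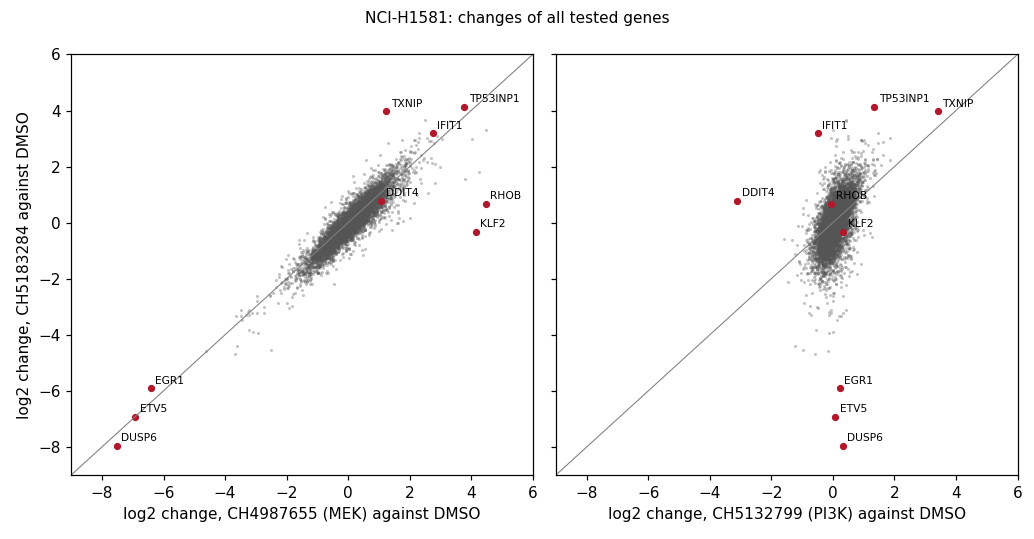
Log2 change with CH5183284 against DMSO (vertical axis) over that with the MEK inhibitor CH4987655 (left) and the PI3K inhibitor CH5132799 (right) for 9528 genes in NCI-H1581, 1 point per gene, with the line of equal change. KLF2 and RHOB lie to the right of the line for CH4987655, and DDIT4 is at −3.11 with CH5132799.

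The PI3K inhibitor CH5132799 changed fewer genes, and none of the ERK-dependent transcripts by 2-fold. DDIT4 (REDD1), an inhibitor of mTORC1, fell by 3.11 (SE 0.22), SLC7A5 by 1.47 (SE 0.13), ASNS by 1.18 (SE 0.09), the tRNA ligase gene CARS1 by 1.16 (SE 0.07), the serine synthesis gene PSAT1 by 1.10 (SE 0.06) and HK2 by 1.03 (SE 0.12). MKI67, a proliferation marker, fell by 1.02 (SE 0.18). HK2 and MKI67 changed by −0.42 and −0.50 when the probe sets of a gene were averaged. TXNIP rose by 3.41 (SE 0.23), ARRDC4 by 1.87 (SE 0.15), KLHL24 by 1.85 (SE 0.24), the selenium carrier gene SELENOP by 1.43 (SE 0.13), NDRG1 by 1.29 (SE 0.15) and IGF1R by 1.19 (SE 0.17). Averaging probe sets brought TXNIP to 1.86 and KLHL24 to 0.86. Of the 13 ATF4 and amino acid genes, 4 fell, 0 rose and 9 were not passed (4 adjusted over the list alone), adjusted p = 1.2e-10 and 0.042 with an estimated correlation. Of the 17 ERK-dependent transcripts, 0 rose and 0 fell. The FOXO list was higher by 0.74 on average with 1 of 10 genes risen, adjusted p = 2.7e-04 and 0.084 with an estimated correlation. In all, 58 genes rose and 14 fell.

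Against CH5132799, CH5183284 differed in 865 genes, 349 higher and 516 lower. DUSP6 was lower by 8.28 (SE 0.14), ETV5 at least 128-fold, EGR1 by 6.14 (SE 0.16), MCM7 by 1.81 (SE 0.08), TRIB3 by 1.72 (SE 0.17) and IGF1R by 1.56 (SE 0.17). DDIT4 was higher by 3.88 (SE 0.22), IFIT1 by 3.68 (SE 0.16), AXL by 1.57 (SE 0.09), the cystine carrier gene SLC7A11 by 1.53 (SE 0.15) and LSS by 1.48 (SE 0.12). Of the ERK-dependent transcripts 15 of 17 were lower, and of the G1/S genes 16 of 22. The 16 sterol and lipid synthesis genes were higher by 0.54 on average, adjusted p = 5.8e-05 and 0.29 with an estimated correlation.

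Across genes, the CH5183284 changes correlated with those of AZD4547 at r = 0.979, of CH4987655 at r = 0.913 and of CH5132799 at r = 0.582. Unchanged groups simulated against the same DMSO arrays gave r = 0.50, so part of these values may come from the shared controls. The covariances were 0.516, 0.448 and 0.133, beside 0.0067 in the simulation. With CH4987655, 456 genes rose and 388 fell with both compounds, against 48.7 and 31.3 for independent lists, and 0 went opposite ways. With CH5132799 the shared calls were 49 and 9, against 4.5 and 1.0. The panel's NCI-H1581 response to CH5183284, which shares no array with these, correlated over 9176 genes with CH5183284 at r = 0.934, AZD4547 at 0.936, CH4987655 at 0.870 and CH5132799 at 0.509. Genes are not independent replicates, so these carry no p.

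The NCI-H1581 response to CH5183284 was measured in both sets. In a fit of these 8 arrays, 1059 genes were called in both sets in the same direction (511 rose, 548 fell) and 0 in opposite directions. The changes correlated at r = 0.938 over 9449 genes. DUSP6 fell by 7.94 (SE 0.18) in the panel, EGR1 by 5.23 (SE 0.26) and ETV5 at least 97.5-fold, to the floor, while CD24 rose by 3.94 (SE 0.16) and AXL by 2.36 (SE 0.20). The limma interaction called 0 genes, with 781 at unadjusted p under 0.05.

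Across the 14 lines, with the line as the replicate, CH5183284 changed these genes. DUSP6 changed by −4.69 (SD over lines 2.32) and fell in 13 lines, all but NCI-N87. ETV5 changed by −3.86 (SD 1.80) and fell in 13 lines, all but SNU-16. Its call in NCI-N87 is lost on that line's own arrays, without 1 array and as the mean of its probe sets (−0.26). SPRED1 (−1.41, SD 0.71) and SPRED2 (−2.11, SD 1.17) fell in 11 lines each, as did the lipoprotein receptor gene LRP8 (−2.13, SD 1.46) and TRIB3 (−1.57, SD 0.84). ETV1 (−2.02, SD 1.39; −0.66 as the mean of its probe sets) fell in 9 lines, DUSP4 (−1.50, SD 1.03) in 8, SPRY4 (−1.82, SD 1.76) in 7 and ETV4 (−1.30, SD 1.48) in 6. Of 20 ERK-dependent transcripts, 17 were lower, 0 higher and 3 not passed at adjusted p under 0.05 (18 lower and 1 higher adjusted over the list alone), with a list test at adjusted p = 1.9e-09, or 0.11 with an estimated correlation. EGR1 was not called across lines (SD over lines 2.64, adjusted p = 0.15): it rose in RT-4 and UM-UC-14 and fell in 6 lines, and without RT-4 it was called lower, at −1.65. EPHA4 was not called either (0.50, SD 0.95) and rose in 3 lines.

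H2AC6, a histone gene, changed by 1.99 (SD 1.40) and rose in 12 lines. KLHL24 (4.42-fold in the mean), SELENOP (2.18, SD 1.42), YPEL5 (1.87, SD 1.34) and YPEL2 (1.84, SD 1.09) rose in 11 lines each, TP53INP1 (2.31, SD 1.84) and CCNG2 (1.60, SD 1.02) in 10. Of 18 FOXO targets 13 were higher, 0 lower and 5 not passed (14 adjusted over the list alone), among them FOXO3 (0.82, SD 0.48), SESN1 (0.78, SD 0.46) and BCL2L11 (0.87, SD 0.51). The list was not called with an estimated correlation (adjusted p = 0.25). Among receptor genes, FGFR2 was higher by 0.97 (SD 0.86), ERBB3 by 0.93 (SD 1.00), ERBB2 by 0.57 (SD 0.80), INSR by 0.67 (SD 0.95) and IGF1R by 0.43 (SD 0.65). The first 3 rose in 6 lines each. The calls of ERBB2, INSR and IGF1R across lines are each lost without some 1 of the lines. Of 11 other receptor tyrosine kinases 4 were higher, 0 lower and 7 not passed (4 adjusted over the list alone), and the list was not called (adjusted p = 0.10, or 0.37 with an estimated correlation). Of 8 FGF receptors and co-factors 1 was higher and 1 lower, and that list was not called either (adjusted p = 0.65). NDRG1 (1.27, SD 1.13) rose in 9 lines and RBL2, a pocket protein of resting cells, was higher by 0.60 (SD 0.44). The epithelial cadherin gene CDH1 was higher by 0.57 (SD 0.69) and rose in 4 lines. Of 17 interferon response genes 7 were higher and 0 lower (8 adjusted over the list alone), such as IFI6 (1.22, SD 1.01) and HLA-B (0.54, SD 0.38), in a list not called with an estimated correlation (adjusted p = 0.25).

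Members of the replication, mitosis and ribosome lists were lower across lines, but none of these lists was called with an estimated correlation (adjusted p = 0.25, 0.26 and 0.25). All 22 G1/S and DNA replication genes were lower, for example CDC25A (−1.44, SD 1.00), TYMS (−1.21, SD 0.93), MCM7 (−1.19, SD 0.82) and CDT1 (−0.70, SD 0.46), while MCM10 (−2.06, SD 1.65) fell in 10 lines. Of 23 G2 and mitosis genes 18 were lower and 0 higher (21 adjusted over the list alone), such as MKI67 (−1.10, SD 0.77) and CCNA2 (−0.92, SD 0.75). Of 19 members of the ribosome biogenesis list 18 were lower, among them NOP16 (−1.34, SD 1.05). SRM, a spermidine synthase gene that the list also holds and not a ribosome factor, was lower too (−1.21, SD 0.87). Of 18 ATF4 and amino acid genes 11 were lower, including PSAT1 (−1.04, SD 1.01) and MTHFD2 (−0.78, SD 0.58), adjusted p = 0.25 with an estimated correlation. HK2 was lower by 1.09 (SD 0.84). Of 15 sterol and lipid genes 6 were lower, such as SCD (−0.67, SD 0.85), FASN (−0.63, SD 0.79) and FDPS (−0.53, SD 0.62), adjusted p = 0.42 with an estimated correlation. In the BCL2 family, PMAIP1 was lower (−1.24, SD 0.94; fell in 8 lines), as was BCL2 (−0.56, SD 0.73), and BIK was higher (0.87, SD 1.16). The calls of BCL2 and BIK are lost with no filter. CCND3, the G1 cyclin D3, was lower by 0.93 (SD 0.71). It was the only lower one of the 12 members of the cell cycle inhibitor and quiescence list, and is itself not an inhibitor. In that list 7 were higher and 4 not passed (list test, adjusted p = 0.030, or 0.25 with an estimated correlation). Of 8 reference genes 5 were lower, including HPRT1 (−0.69, SD 0.61) and TFRC (−0.59, SD 0.59), adjusted p = 0.25 with an estimated correlation.

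The smallest p across lines belonged to HSD17B12, an enzyme of fatty acid elongation, at −0.57 (SD 0.16; adjusted p = 1.8e-05), which was lower in all 14 lines and under 2-fold in the mean. In all, 2314 genes were higher and 2115 lower across lines at adjusted p under 0.05 of 11999 tested, and 63 and 131 of these by at least 2-fold in the mean. The list test called 10 of 16 lists across lines, and 0 of 16 with an estimated correlation.

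By line, the lists were tested in the shared fit of all panel arrays, and not on each line's own arrays alone. In these tests the ERK-dependent transcripts were lower in 14 of 14 lines, also with an estimated correlation. Their means ran from −2.50 in HSC-39 to −0.19 in RT-4. G1/S genes were lower in 13 lines, all but NCI-N87, and FOXO targets higher in 12. The ribosome biogenesis list was lower in 11 lines, and the cell cycle inhibitor and quiescence list higher in 8. These counts held with an estimated correlation. G2 and mitosis genes were lower in 10 lines and higher in MFE-280, where the mean was 0.29. ATF4 and amino acid genes were lower in 10 lines, 7 with an estimated correlation, most in RT-4 with a mean of −1.64. Sterol and lipid genes were lower in 9 lines, 8 with an estimated correlation, and higher in DMS-114 and RT-4. Interferon genes were higher in 7 lines, 6 with an estimated correlation. The reference genes were lower in 4 lines, HSC-39, KATO-III, NCI-716 and SNU-16.

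**Figure D3:**
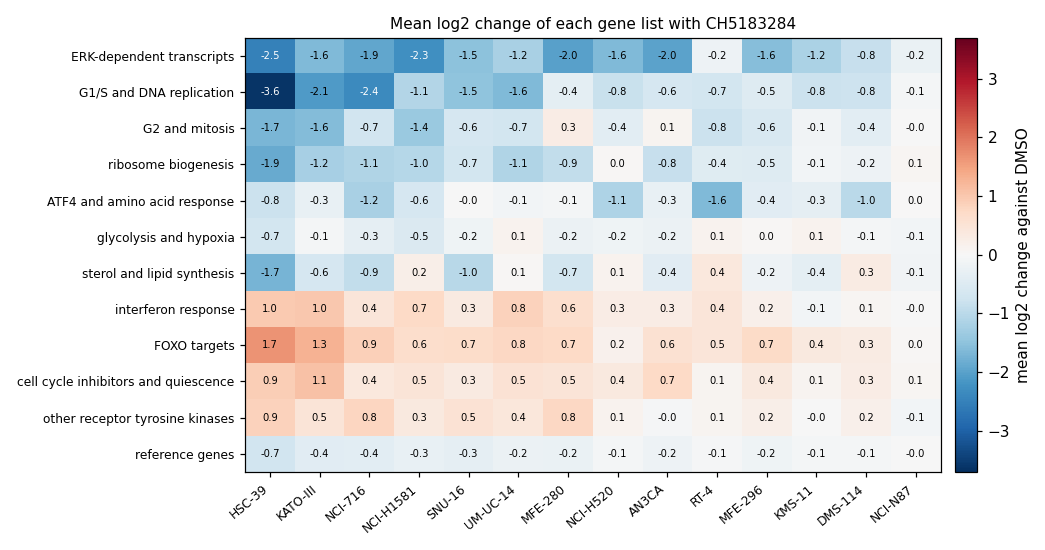
Mean log2 change with CH5183284 against DMSO (colour and printed value) of the members of each gene list (vertical axis) in each line (horizontal axis, ordered by number of called genes, 2 arrays per group). The ERK-dependent transcripts run from −2.50 in HSC-39 to −0.19 in RT-4.

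The number of called genes ran from 71 in NCI-N87 to 3265 in HSC-39. In HSC-39, DUSP6 fell by 6.96 (SE 0.18), the replication factors MCM10 at least 66.2-fold and GINS2 by 5.04 (SE 0.10), and IER3 by 5.40 (SE 0.21), and EGR1 fell by 4.71 (SE 0.26). TP53INP1 rose by 6.15 (SE 0.21), the B cell adaptor gene BLNK by 5.91 (SE 0.18), TUBA1A by 5.80 (SE 0.10) and ERBB3 by 2.71 (SE 0.15). In KATO-III (2030 genes), DUSP6 fell by 4.74 (SE 0.18) and the chemokine CXCL8 by 4.11 (SE 0.15), while the phospholipase gene PLA2G2A rose by 5.03 (SE 0.26), TP53INP1 by 4.88 (SE 0.21) and the CDK inhibitor CDKN1C (p57) by 4.83 (SE 0.22). In SNU-16 (1245 genes), DUSP6 fell 63.9-fold, ANXA10 by 4.46 (SE 0.27) and UPK1B by 3.71 (SE 0.25), and the fibrinogen gene FGB rose by 3.61 (SE 0.08). In NCI-716 (1524 genes), ETV5 (−6.35, SE 0.18), the mucin MUC2 (−4.36, SE 0.35) and the nucleotide reductase gene RRM2 (−4.26, SE 0.09) fell, while SPOCK3 rose by 4.92 (SE 0.27) and the clotting factor gene F10 at least 21.0-fold, from the floor.

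In the urothelial line UM-UC-14 (1233 genes), DUSP6 fell by 3.76 (SE 0.18) and TLR4 at least 20.2-fold, to the floor, while SST (somatostatin) rose at least 35.5-fold, from the floor, and CD86 rose by 4.58 (SE 0.15). In RT-4 (487 genes), also urothelial, ETV5 fell by 2.95 (SE 0.18) and DUSP6 by 1.04 (SE 0.18), a value of −0.91 without 1 array. STC2, a target of ATF4, fell by 3.46 (SE 0.19), CTH by 2.83 (SE 0.13) and SLC7A5 by 2.47 (SE 0.11), while EGR1 rose by 4.56 (SE 0.26) and COL3A1 by 3.03 (SE 0.14), or 1.12 as the mean of its probe sets. In the endometrial lines, ETV5 (−5.42, SE 0.18), SPRY4 (at least 39.5-fold) and MYC (−3.00, SE 0.09) fell in AN3CA (578 genes), and HOGA1 rose by 3.26 (SE 0.23). In MFE-280 (913 genes), ETV5 fell by 4.87 (SE 0.18) and SPRY1 by 3.97 (SE 0.23). There the BMP and WNT antagonist SOSTDC1 rose by 4.55 (SE 0.25) and KLHL1 by 4.15 (SE 0.08). FGFR2 rose by at least 3.16 (SE 0.15), or 0.75 as the mean of its probe sets. Its log2 level in the DMSO arrays of MFE-280, −5.06 from the line median of 8.59, lay near the floor. In MFE-296 (339 genes), DUSP6 fell by 5.22 (SE 0.18), ETV5 at least 42.2-fold, to the floor, and SPRED2 by 4.09 (SE 0.16), while IGFBP5 rose by 3.55 (SE 0.16; 1.62 as the mean of its probe sets) and TXNIP by 2.96 (SE 0.13).

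Among the lung and plasma cell lines, CTLA4, an immune checkpoint gene (at least 108-fold), DUSP6 (−6.93, SE 0.18) and RGS4 (at least 35.0-fold) fell in NCI-H520 (587 genes). There the WNT antagonist DKK3 rose by 5.33 (SE 0.25) and IGF1, a growth factor, from a level of 6.26 to 10.26. In DMS-114 (190 genes), DUSP6 fell by 3.56 (SE 0.18), SPRED2 by 3.15 (SE 0.16), ETV1 by 2.98 (SE 0.20) and TRIB3 by 2.83 (SE 0.12), and MAF rose by 2.12 (SE 0.17). ETV1 changed by −0.76 there as the mean of its probe sets. In KMS-11 (239 genes), DUSP6 fell by 6.57 (SE 0.18), CCL5 at least 12.4-fold, to the floor, and the integrin gene ITGB7 by 2.87 (SE 0.09), while TGFB2 rose by 2.95 (SE 0.17). In the gastric line NCI-N87 (71 genes), KRT13 fell by 2.49 (SE 0.25), CYP1B1 by 2.12 (SE 0.23) and ADGRF1 by 1.70 (SE 0.11), while LARGE2 rose by 1.87 (SE 0.27) and RAPGEFL1 by 1.49 (SE 0.07). ADGRF1 changed by −0.97 as the mean of its probe sets. Fitted on its own 4 arrays, NCI-N87 had 2 called genes, and the calls of KRT13, ADGRF1 and RAPGEFL1 were lost. ERBB2 mRNA in its DMSO arrays was 174-fold over the median of the 14 lines.

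**Figure D4:**
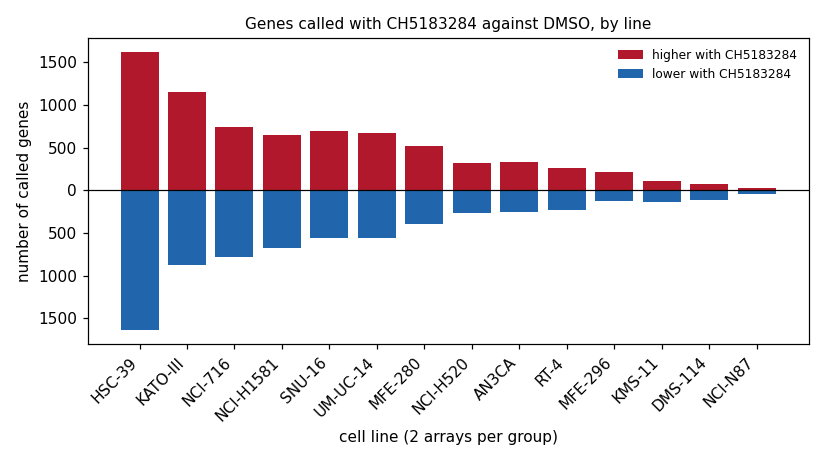
Number of genes called higher (above 0) and lower (below 0) with CH5183284 against DMSO in each of 14 lines (bars, 2 arrays per group, 11999 genes tested). HSC-39 has 1624 higher and 1641 lower, NCI-N87 23 and 48.

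A limma F test of equal change in the 14 lines passed for 10233 of 11999 genes, and 509 genes rose in 1 line or more and fell in another. FGFBP1, a carrier that releases FGFs, rose by 3.67 (SE 0.34) in NCI-H520 and by 1.75 (SE 0.34) in RT-4 and fell by 3.53 (SE 0.34) in SNU-16 and 2.43 (SE 0.34) in KATO-III. DDIT4 rose by 2.31 (SE 0.11) in UM-UC-14 and fell by 1.74 (SE 0.11) in KMS-11. The FGFBP1 change in RT-4 was 0.95 without 1 array. EGR1 rose by 1.03 (SE 0.26) in UM-UC-14, or 0.71 as the mean of its probe sets.

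Genes called lower with CH4987655 and not with CH5132799 in the inhibitor set were lower with CH5183284 in 13 of the 14 lines (405 genes, mean over lines −0.58, SD 0.38). Those called higher with CH4987655 and not with CH5132799 were higher in 13 (546 genes, 0.44, SD 0.29). Both counts were 13 with an estimated correlation, and the exception was NCI-N87 (−0.01 and 0.02). NCI-H1581, the line these lists came from, is among the 13. The 16 genes called higher with CH5132799 and not with CH4987655 were higher in 10 lines, NCI-H1581 among them (0.64, SD 0.49), also with an estimated correlation. Tested across lines with an estimated correlation, none of these 3 lists was called (adjusted p = 0.059, 0.071 and 0.11). The 6 measured genes called lower with CH5132799 and not with CH4987655 were lower in 4 lines, and in 0 with an estimated correlation.

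Before treatment, FGFR3 mRNA in KMS-11 was 171-fold over the median of the lines, FGFR2 in SNU-16 57.1-fold and in HSC-39 14.3-fold, and FGFR3 in UM-UC-14 18.6-fold. For FGFR1 the probe set with the highest mean varied by 0.88 over lines and another by 7.80. By the latter, chosen after seeing the data, FGFR1 was 141-fold over the median in AN3CA, 75.6-fold in NCI-H520, 21.0-fold in DMS-114 and 18.0-fold in NCI-H1581. Whether the median level of that probe set lies near the floor was not checked, so these folds may be minimums. The largest excess of FGFR1 to FGFR4 had no detectable relation over 14 lines to the mean change of the ERK-dependent transcripts (Pearson r = 0.01, permutation p = 0.98) or to the number of called genes (r = 0.14, permutation p = 0.62). The adjusted p over these 4 relations, Spearman values included, was 0.91 to 0.98. With the FGFR1 probe set that varies, the signs changed, to r = −0.23 and −0.17 (permutation p = 0.43 and 0.56). Without KMS-11 and SNU-16, the lines farthest out, r was −0.13 and 0.51 (permutation p = 0.70 and 0.090).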

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

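The test of the difference between the MEK and FGFR inhibitors against the PI3K response, the count of 2-fold changes at any p, the count of genes with no other probe set and the relation with the second FGFR1 probe set were chosen after the result was seen. EGR1, FGFBP1 and DDIT4 were picked as examples after their values were seen. The other tests in this part were written down before their results were seen.

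The response to CH5183284 differed between lines, judged against the spread between the 2 arrays of a group, which may be technical. A gene at the floor in some lines cannot fall there and has a lowered shared spread, which can raise the number that pass. The F test passed for 10233 of 11999 genes, and 509 genes rose in 1 line or more and fell in another. EGR1 rose by 4.56 in RT-4 and fell by 5.23 in NCI-H1581. The treated RT-4 arrays had the lowest replicate correlation of the panel (0.9934). FGFBP1 rose by 3.67 in NCI-H520 and fell by 3.53 in SNU-16. DDIT4 rose by 2.31 in UM-UC-14 and fell by 1.74 in KMS-11.

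The number of called genes was 46.0 times as high in HSC-39 (3265) as in NCI-N87 (71). Counted at any p, 3265 genes changed at least 2-fold in HSC-39 and 81 in NCI-N87, a ratio of 40.3, so spread between replicate arrays did not hide such changes in NCI-N87. The ratio was 47.1 after quantile normalization, so differences in distribution left between the deposited arrays are not the whole cause. Quantile normalization of deposited values cannot undo what was done to them before, so an effect of the earlier normalization stays open. The bar against spread, set before, had 2 parts. The first was no clear negative Spearman rho of spread with the number of called genes, which was −0.31 (permutation p = 0.28). The second was a ratio above 2 with each line on its own arrays, which was 1491. Both were met, but the second cannot decide. NCI-N87 has the largest spread (0.217) and loses calls in that fit whatever the cause. HSC-39 and DMS-114 had similar spreads (0.198 and 0.202) with 3265 and 190 called genes, and MFE-296 the smallest (0.160) with 339. For these lines the values argue against spread as the whole cause. A smaller part over all 14 lines stays open. The level of FGF receptor mRNA before treatment stays open, with r = 0.14 over 14 lines (permutation p = 0.62) and r = −0.17 with the FGFR1 probe set that varies (permutation p = 0.56), which 14 lines cannot decide, and the identity of the lines stays open as well.

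Probe sets without a single gene symbol were tested in the same fits, outside the comparisons of genes. With CH5183284 in NCI-H1581, 274 of 2233 such probe sets were called, and 3 against AZD4547. In the panel the counts ran from 12 of 3008 in NCI-N87 to 644 in HSC-39.

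CH5183284 and the MEK inhibitor CH4987655 differed in 73 genes, KLF2, RHOB and TXNIP among them. A single array is not the cause, since leaving out each of the 10 arrays left at least 65. For 12 of these genes a disagreement in direction between probe sets is excluded, since 100% of their 17 other probe sets had the same sign of difference. Whether the sizes agree was not tested. The other 61 had no other probe set past the filter, so for them disagreement between probe sets stays open. Over the 73 genes the difference correlated with the CH5132799 change at r = 0.62, with the same sign in 75.3% of them, although no array is shared. A part of the FGFR response that runs through PI3K is a possible explanation for some of these genes, found and tested on the same data. TXNIP rose with CH5183284 and CH5132799 (3.97 and 3.41) and less with CH4987655 (1.24), by its probe set with the highest mean. Its other probe sets changed by 2.46 and 1.24 with CH5183284 and by 1.44 and 0.75 with CH5132799. With CH4987655 they changed by 0.29 and −0.60, so a rise of TXNIP with that compound rests on 1 probe set. RHOB and KLF2 instead rose with CH4987655 (4.48 and 4.14). They changed by 0.67 and −0.32 with CH5183284 and by −0.06 and 0.33 with CH5132799. For such genes the difference is a rise with CH4987655, which that explanation does not cover. How many of the 73 are of each kind was not counted. The ERK-dependent transcripts differed between CH5183284 and CH4987655 by 0.06 on average (95% interval −0.02 to 0.15) and none by 2-fold. ETV4, ETV5 and FOS lay at or near the floor with both and other members went both ways, such as ETV1 (0.73) and IER3 (−0.63), so a different block of MEK stays open.

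Across the 14 lines, 4429 genes passed with the real labels. Swapping treated and control within random lines gave at most 0 genes in the 99 other splits of 100 drawn. Only the real split reached its count, 1 of 100, which is the smallest share that 100 splits can give. Chance is thus unlikely as the cause, but a test of this size cannot exclude it.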

How the results depend on the processing

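Chosen after seeing the data were the alternatives for the F test, the similarities, both NCI-H1581 sets and the quantile and leave-one-out versions of the lists, the estimated correlation for the compound-derived lists and the second FGFR1 probe set. No called result changed direction. The 247 results of named genes (a gene in a comparison) gave 4042 recomputed values, of which 3990 kept their side of the threshold, 49 lost it and 3 gained it. The 345 list tests, each recomputed in 2 ways, gave 690 values, of which 635 kept theirs and 55 lost it, 52 of them with an estimated correlation, which left 14 of 45 calls in the inhibitor set and 0 of 10 across lines. The genes lower with CH5132799 were lower in 0 lines in place of 4 with it, and in 10 with genes called with both compounds kept. Numbers of called genes stayed within 1.5 times, with these exceptions. NCI-N87 had 41 with the filter at log2 7 and 2 on its own 4 arrays, DMS-114 124 on its own. Across lines, arrays as replicates gave 8854 genes in place of 4429, by construction, since the spread between lines is left out. Without 1 array (a lone array is assumed to vary like the other groups) CH5132799 had 69 to 123, DMS-114 236 to 304 and NCI-N87 90 to 111. The cause was not tested. CH5183284 against AZD4547 stayed at 0 in each alternative. With no filter, the correlations of changes were 0.971 with AZD4547, 0.905 with CH4987655 and 0.909 between the NCI-H1581 sets (0.959 with the filter at log2 7), with 2 genes that differ between these sets. Without 1 array they were 0.962 to 0.980, 0.902 to 0.917, 0.544 to 0.612 for CH5132799 and 0.917 to 0.936 between the sets, with 0 to 1 genes. With the second FGFR1 probe set, r with the number of called genes was −0.17. As a replicate block, the replicate number gave 1451 genes for CH5183284 and 73 for CH5132799, changed no count by 1.5 times and no call of a named gene. Between groups, replicate differences correlated at −0.15 to 0.32 in the inhibitor set (1 of 10 pairs over 0.1) and −0.06 to 0.13 in the panel (2 of 14). These values show no clear pairing by replicate number, but cannot exclude one. Quantile normalization moved the share of higher genes among calls most for CH5132799, by −5.93 points. Over 50% of probe sets lie at the floor, so a fall to it is a minimum.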

Other observations

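The lysosome and autophagy list was put together after GRN, PSAP and GABARAP were seen among the genes with the smallest p across lines, and its tests were fixed before their results were seen. The line marker lists were fixed before the data.

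GRN (progranulin) was higher by 1.23 (SD over lines 0.67) and rose in 8 lines, the autophagy protein gene GABARAP was higher by 0.79 (SD 0.39) and PSAP (prosaposin) by 0.76 (SD 0.41). Among the untreated lines, plasma cell markers were highest in KMS-11, with a mean log2 excess of 5.59 over the median of the lines. Neuroendocrine markers were highest in NCI-716 (7.58), followed by NCI-H520 (2.70) and SNU-16 (2.34). Urothelial markers were highest in RT-4 (5.22) and UM-UC-14 (3.95), followed by NCI-N87 (2.33), which is gastric. Gastric or intestinal markers were highest in SNU-16 (4.92), KATO-III (3.53) and HSC-39 (3.24), with NCI-N87 not among them. Endometrial markers were highest in MFE-280 (3.33), followed by RT-4 (1.53) and DMS-114 (1.17), which are not endometrial. Leukocyte markers were highest in KMS-11 (3.77) and in the urothelial line UM-UC-14 (3.42). Fibroblast markers were highest in NCI-H1581 (6.77) and DMS-114 (5.36). These are levels without a test.

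The hypothesis that lysosome and autophagy genes rise with CH5183284 was tested on 25 further genes, with GRN, PSAP and GABARAP left out. Across lines 17 of them were higher and 0 lower, with a mean of 0.37 (camera p = 1.8e-06, or 0.087 with an estimated correlation). By line the list was higher in 11 of 14 lines, and in 8 with an estimated correlation, from −0.01 in NCI-N87 to 0.84 in NCI-716. With the MEK inhibitor in NCI-H1581 the list of 26 was higher by 0.63 (camera p = 2.8e-06, or 0.052 with an estimated correlation) and 3 genes rose. Both tests met their prediction with the preset correlation and neither did with the estimated one. In NCI-H1581 the list was lower with CH5183284 than with CH4987655, by 0.29 (95% interval −0.40 to −0.18). The shares that come from loss of ERK activity and from slower growth were not tested and stay open.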
